A study of Mus musculus with 18 samples.

How the data were processed

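Cells of mouse mammary gland were sorted by flow cytometry into the mature luminal (ML) gate and a second gate (N), and RNA was extracted with the RNeasy Micro Plus kit. Sequencing libraries were made from cDNA with the Nextera XT kit, per the labels. The labels give the tissue source of all samples, the N gate included, as mature luminal cells. The genome build was GRCm38 in the submitters' processing notes. The aligner, the counting tool, the gene annotation and whether counting used the strand are not given in the sources used here.

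Each deposited table holds 52636 genes with a count, a width and an RPKM value per gene. The count column holds whole numbers and was read as the read count per gene that the authors deposited. The RPKM column was made by the authors from count, width and a library total that is larger than the sum of the counts (the counts make up 87.4 to 90.4% of it). The width equals the whole span of the gene, introns included, for 44954 (85.6%) of the genes matched to the annotation, and lies within 1% of it for 92.2%. RPKM therefore divides by more than the exons and was used in no test. Of the gene identifiers 52489 (99.7%) matched GENCODE release M21, which gave symbols and coordinates. The 147 others held at most 0.00902% of any library's counts. In all, 163 identifiers shared their symbol with at least 1 other.

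Reads in overlapping genes appear to have been left out of the counts. Of 1216 protein-coding genes that lie inside the span of another gene, 1099 (90.4%) had no count in any library, against 3086 of 20680 others (14.9%). Genes at 0 for this or another reason include Tff3, Elf3, Csn3, B2m, Cox4i1, Ms4a1 and Igkc, 27 entries of the gene lists in all. Values of 0 for such genes say nothing about expression.

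The groups (3 genotypes by 2 gates, 3 libraries each), the tests, the gene lists and the rule for named genes were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 6 groups (minimum count 10, minimum total 15), which left 18298. Libraries were scaled by TMM (factors 0.850 to 1.10), and CPM values and floors use the library totals times these factors. A single quasi-likelihood model with 6 group means and 12 residual degrees of freedom was fitted (common dispersion 0.425, biological coefficient of variation 0.652), and each comparison was a contrast in it. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a contrast, and genes with an adjusted p under 0.05 are called. Standard errors come from the model's log2 coefficients. Principal components, and correlations between libraries unless stated otherwise, used log2 of CPM + 1 for the 10000 most expressed genes.

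Comparisons were N against ML in each genotype and over the 3 genotypes with equal weight, the genotypes within the N gate and within the ML gate, and the interaction of gate with each mutant genotype. Comparisons against the same WT libraries are not independent of each other. In the comparison over genotypes the named genes are the 8 highest and 8 lowest log2 fold changes among called genes with the same sign in each genotype and an average log2 CPM of at least 3. In other comparisons they are the 5 highest and 5 lowest called genes at that level, and 3 and 3 for interactions. Predicted genes and clone names were passed over. Up to 4 members of each list with the smallest p were also eligible, and 21 genes of hormone response, luminal and basal identity were named whatever their values. Further list members in the text, and the choice of those that kept their call with each library left out, were chosen after their values were seen.

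Gene lists (39) covered estrogen and progesterone response, hormone-sensing luminal, luminal progenitor, milk, pan-luminal, basal and keratinocyte genes, mesenchymal transition, signalling, stress and metabolic pathways, and markers of 11 other cell types. They were tested with camera of limma 3.58.1, with the correlation between genes estimated and Benjamini-Hochberg adjustment over the lists. Camera with a preset correlation of 0.01 was an alternative. Lists of hair follicle keratins, epidermal differentiation and immunoglobulin genes were added after the data were seen and were counted but not tested.

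Replicates differed by more than counting error (chi-square per degree of freedom of at least 45.7) and correlated within groups at r = 0.904 to 0.987. Whether equal library numbers pair the samples was checked from deviations from the group means. All 9 pairs of N and ML libraries with the same number and genotype correlated at 0.168 to 0.556, and each library but WT N 2, which correlated at 0.193 with WT ML 1, correlated best with its own number (other pairs −0.456 to 0.193). The numbers were therefore taken to pair N with ML libraries within a genotype. This comes from the data, since the labels do not say that such libraries share an animal. Across genotypes equal numbers correlated at −0.543 to 0.298 and do not pair the libraries. The main model has no pairs, as fixed beforehand, and a model with the pair (or, between genotypes, the library number) as a block was an alternative.

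Other alternatives were DESeq2 size factors within edgeR, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, a model of only the groups compared, and each library left out in turn. After the data were seen, 2 more were added: the mean log2 level of Krt1, Krt10 and Krtdap as a covariate (the epidermal covariate), and a fit without 5 libraries in doubt. Those libraries were WT N 3, Y541S N 3, WT ML 1, WT ML 2 and Y541S ML 3. The fit without them holds WT ML 3 as the only WT ML library. The effects of the alternatives are given in the closing part. For a gene with no count in a whole group, the fold is a lower bound against 3 counts per library.

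The model was tested on simulated data with the dispersion of these libraries, in which 50 genes were changed at each fold size. The changed genes were drawn from those with a mean count of at least 50. Counts were drawn independently for each gene, with no outlying library and no pairs. Recovery in the real libraries, and of genes with fewer counts, may therefore be lower. For N against ML over the genotypes edgeR recovered 44, 90, 98 and 96% of genes changed 2-, 4-, 8- and 16-fold, with 5 unchanged genes called. Within WT these were 12, 50, 80 and 84% (1 unchanged gene called), within D542G 16, 46, 78 and 82% (2) and within Y541S 8, 52, 74 and 76% (2). Between genotypes in the N gate they were 0, 50, 74 and 80% for D542G against WT (3), 8, 50, 74 and 80% for Y541S against WT (1) and 6, 48, 68 and 82% for the mutants (5). In the ML gate they were 2, 44, 68 and 82% (2), 6, 54, 72 and 84% (3) and 8, 44, 74 and 80% (1) in the same order. For the interactions they were 0, 24, 52 and 72% for D542G (4) and 2, 26, 54 and 64% for Y541S (2). DESeq2 called 59 to 93 unchanged genes in these simulations and limma-voom 0 to 5. Camera with an estimated correlation called 0 of 100 random lists. Their genes were simulated independently, so this does not test lists of genes that vary together.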

Results

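RNA was sequenced from cells that had been sorted by flow cytometry from the mammary glands of mice. The 18 libraries form 6 groups of 3 biological replicates. Mice were wild type (WT) or carried 1 of 2 mutations of Esr1, the gene of estrogen receptor alpha (ERα), named D542G and Y541S for the amino acid they change. Cells of each genotype came from a mature luminal gate (ML) and from a second gate, called N here. All mice, 6 months old, carried pellets of E2 and P4 (estradiol and progesterone) and then received giredestrant, an ERα antagonist, by mouth at 30 mg/kg each day for 4 days. No library came from mice without the antagonist, so its own effect was not compared. Each library held 34797778 to 49507144 gene counts, with 18353 to 20807 genes at 1 count or more. The study's title asks whether cells that appear under ERα antagonism are also present, as a rare population, in WT tissue, and the N and ML gates were compared in each genotype with that question. Values are CPM (gene counts scaled to an equal library total after TMM normalisation) as mean ± SD over 3 libraries, or log2 fold changes ± standard error. P-values measure the spread between libraries, and floors on counts of 0 cover counting error only.

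Esr1 (ENSMUSG00000019768, chromosome 10 4611593–5005614, + strand of GRCm38) is the gene that carries the mutations. Gene counts cannot show which amino acid was encoded. Esr1 stood at 253 ± 178 CPM in WT ML, 181 ± 31.2 in D542G ML and 144 ± 114 in Y541S ML libraries. In the N gate it stood at 111 ± 169.8, 267 ± 40.6 and 76.5 ± 32 CPM. The 3 WT N libraries held 10.7, 14.9 and 307 CPM. No comparison between gates called Esr1 in the main model (N against ML, mean of the 3 genotypes, −0.51 ± 0.55, adjusted p = 0.529). That value was −1.55 ± 0.34 without WT N 3 (adjusted p = 0.00306), −1.24 by limma-voom (0.00464) and −0.91 ± 0.34 in the paired fit (0.0767). Limma-voom gave WT N 3 the lowest quality weight of all libraries (0.180). Its values for Esr1, here and below, and those without WT N 3 therefore discount the same library and are not separate evidence. Over the alternatives the adjusted p was 0.00306 to 0.853.

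The first principal component held 45.4% of the variance of the 10000 genes used and parted the gates. ML libraries lay between −65.8 and −17.1 on it, and 8 N libraries between 33.1 and 78.5. WT N 3 lay at −7.61, between the gates, and its closest library was WT ML 3 (Pearson r = 0.872 across genes). Y541S N 3 was closest to WT N 2 (r = 0.942), against 0.844 and 0.803 to Y541S N 1 and 2. Krt18, a luminal keratin, stood at 4583 CPM in WT N 3 against 195 and 264 in WT N 1 and 2. Krt14, a basal keratin, stood at 2171 CPM there against 13800 and 19470. Genes of the differentiating epidermis (9 measured, a list chosen after the data were seen) summed to 7417, 14776 and 1147 CPM in WT N 1 to 3 and to 14912 CPM in Y541S N 3. Their sum was 40.1 and 58.7 CPM in the other 2 Y541S N libraries, 70.4 to 1230 CPM in D542G N and 20.7 to 3508 CPM in ML libraries.

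**Figure D1:**
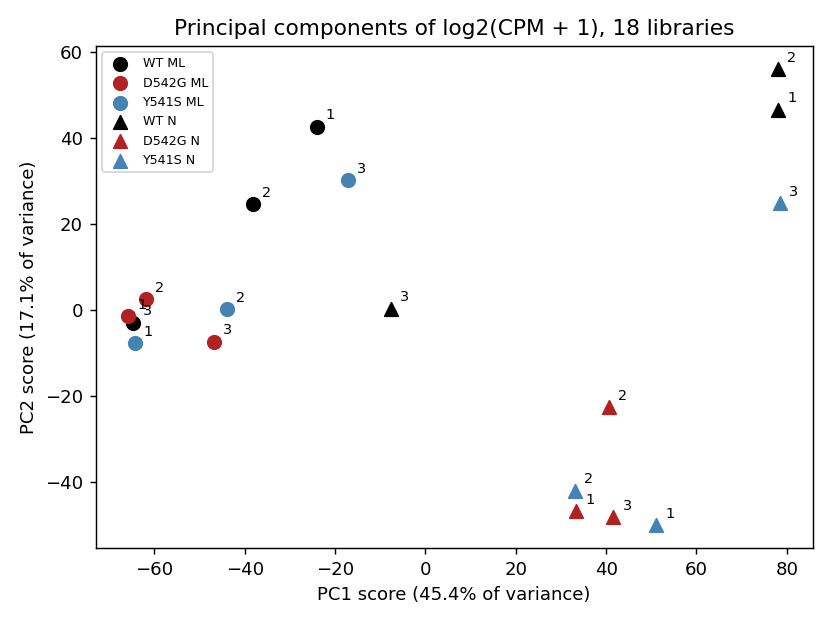
First and second principal components (axes, with the percentage of variance) of log2 CPM for the 18 libraries, 1 point each, coloured by genotype and shaped by gate. Apart from WT N 3 at −7.61, N libraries lie at 33.1 or more on the first component and ML libraries at −17.1 or less.

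The N gate was first compared with the ML gate over the 3 genotypes, with equal weight for each (9 libraries against 9). Genes of basal and myoepithelial cells were higher in the N gate: all 17 measured members of that list rose, and 15 of them lay above the ML median in all 9 N libraries. Among them were Krt14 (4.93 ± 0.71), the contractile genes Acta2 (3.17 ± 0.40), Oxtr (3.33 ± 0.43) and Tagln (1.97 ± 0.26), and the matrix gene Sparc (3.12 ± 0.31). Genes tied to mesenchymal transition rose for 9 of 17 members and fell for none, among them the matrix protease Mmp2 (5.10 ± 0.38), the receptor kinase Axl (4.10 ± 0.34), the transcription factor Snai2 (4.92 ± 0.60) and Vim (2.21 ± 0.29). Genes of luminal progenitors fell for 10 of 15 members and rose for none, with Aldh1a3 at −3.95 ± 0.38, the receptor Kit at −3.59 ± 0.39 and Elf5 at −3.74 ± 0.57. Pan-luminal genes fell for 11 of 15, among them Muc1 (−3.94 ± 0.37), the junction gene Cldn3 (−2.90 ± 0.47) and Krt18 (−2.12 ± 0.51), and 1 rose. Keratinocyte and squamous genes rose for 9 of 17, with Krt15 at 3.90 ± 0.69 and Krt6a at 1.72 ± 0.46, and the epidermal genes named above differed widely between N libraries. All genes given with values had adjusted p ≤ 0.0135, and Krt14, Acta2, Oxtr, Tagln, Sparc, Mmp2, Axl, Aldh1a3, Kit and Muc1 lay on the same side of the ML median in 9 of 9 N libraries.

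The gene set test called the basal list (adjusted p = 0.00960 with an estimated correlation) and the mesenchymal list (adjusted p = 0.0221 with an estimated correlation). With same-numbered N and ML libraries of a genotype as pairs, neither was called (adjusted p = 0.0809 for each), and the keratinocyte list was (adjusted p = 0.0166, against 0.462 without pairs). The luminal progenitor and pan-luminal lists were not called (adjusted p = 0.0807 and 0.0617 with an estimated correlation). Adjusted over the list alone, 17 basal, 9 mesenchymal and 10 keratinocyte genes rose, and 11 luminal progenitor and 11 pan-luminal genes fell.

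By fitted fold, the largest increases that had the same sign in each genotype were those of the norepinephrine transporter Slc6a2 (ENSMUSG00000055368, 8.16 ± 1.03), Il22ra2, the Notch regulator Dlk2 (ENSMUSG00000047428, 7.07 ± 0.86), the calcium sensor Vsnl1 (ENSMUSG00000054459, 6.97 ± 0.35), Gpha2 (6.77 ± 1.12), Serpinb7 (6.60 ± 1.83), Serpinb10 (6.58 ± 1.55) and the decoy receptor Il1r2 (6.25 ± 1.12). Il22ra2 was at 0 in all D542G ML libraries and, with a floor of 3 counts per library there, at least 359-fold higher in N by mean CPM (174-fold without WT N 1). Slc6a2, Dlk2, Vsnl1, Gpha2 and Serpinb10 lay above the ML median in 9 of 9 N libraries, Il1r2 in 8 of 9, and Il22ra2 and Serpinb7 in 6 of 9. The calls of Il22ra2 and Serpinb7 were lost without Y541S N 3 (adjusted p up to 1), and that of Serpinb7 also without D542G N 2. The 8 largest decreases were all of immunoglobulin gene segments, each at 0 in all N libraries of at least 1 genotype, where the same floor was used. Ighg2c was at 0 in all 9 N libraries and at 253 ± 369 CPM in the 9 ML libraries, at least 3534-fold lower in N against the floor (0.0715 CPM). It had a count in 7 of the 9 ML libraries, and without WT ML 2, at 1058 CPM, the bound was 2126-fold. Igkv1-117 was also at 0 in all N libraries and at least 266-fold lower (138-fold without WT ML 2 at 92.0 CPM). It had a count in 6 of 9 ML libraries, and its call was lost without D542G ML 1 or Y541S ML 2 (up to 0.14). Ighg2b (at least 2290-fold lower, 1515-fold without Y541S ML 2) kept its call with each library left out in turn. Of the others, Ighg1 (at least 3392-fold, 1176-fold without Y541S ML 2) lost its call without Y541S ML 2 (adjusted p 1), Igkv1-110 (at least 1001-fold, 585-fold without WT ML 1) without D542G ML 2 or Y541S ML 2 (up to 1) and Igha (at least 732-fold, 66.6-fold without Y541S ML 2) without WT N 1, D542G ML 3 or Y541S ML 2 (up to 1). Ighv11-2 (at least 129-fold, 81.8-fold without Y541S ML 2) lost it without D542G ML 2, D542G N 2 or 3 or Y541S ML 2 (up to 1) and in the paired fit (adjusted p = 0.119), and Igkv14-126 (at least 58.8-fold, 40.9-fold without WT ML 1) without any 1 library other than WT ML 2, WT ML 3, WT N 3, D542G ML 1, D542G ML 3, D542G N 1, Y541S ML 1 and Y541S ML 3 (up to 1) and in the paired fit (0.0990). Ighg2c, Ighg2b, Ighg1 and Igkv1-117 lay below the ML median in 9 of 9 N libraries, Ighv11-2 and Igkv14-126 in 8 and Igkv1-110 in 6. Igha, with a count in only 4 of 9 ML libraries, lay below it in 0 of 9 N libraries and above it in 2. Segments of 1 family share sequence, so the assignment of reads among them is uncertain.

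Hormone-related genes were read for the same comparison. Of 22 measured estrogen-responsive genes, 6 rose and 8 fell (8 and 8 adjusted over the list alone), and the set was not called (adjusted p = 0.765 with an estimated correlation). Greb1, a direct ERα target, rose (1.84 ± 0.27, above the ML median in 8 of 9 N libraries), as did Igfbp4 (3.36 ± 0.37), Rerg (1.56 ± 0.24) and Myb (1.77 ± 0.43). Ccnd1, the cyclin of early cell cycle, fell (−2.50 ± 0.23, 9 of 9 N libraries below the ML median), with Prlr (−2.71 ± 0.50), Cited1 (−2.63 ± 0.67) and Rasd1 (−1.22 ± 0.14). Pgr stood at −0.66 ± 0.60 (adjusted p = 0.449), Areg at −0.06 ± 0.35 (0.927) and Foxa1 at −0.88 ± 0.65 (0.342). In the paired fit Foxa1 was called at −1.52 (adjusted p = 0.0477). Of 15 progesterone-responsive genes 2 rose, among them Id4 (2.92 ± 0.50), and 6 fell, among them Calca (−5.13 ± 1.03), Rspo1 (−2.43 ± 0.36) and Lif (−1.89 ± 0.26), with the same counts adjusted over the list alone (set adjusted p = 0.255 with an estimated correlation). Genes of hormone-sensing mature luminal cells fell for 8 of 20 by either adjustment and rose for none (set 0.462). They held Gata3 (−1.26 ± 0.22), Prom1 (−2.30 ± 0.63) and Ly6a (−1.53 ± 0.48), whose call was lost without WT ML 3, WT N 1 or 2, D542G ML 1 or 2, D542G N 1, Y541S ML 1 or Y541S N 1 (up to 0.0641) and in the paired fit (0.0593). Other epithelial surface and keratin genes were Epcam (−1.34 ± 0.23), Krt8 (−1.89 ± 0.48), Cd24a (−0.77 ± 0.22), Krt5 (4.56 ± 0.87), Itga6 (1.56 ± 0.20) and Itgb1 (0.51 ± 0.14), all called. Itga2 (0.52 ± 0.33, adjusted p = 0.261) and Itgb3 (−0.03 ± 0.74, 0.995) were not.

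**Figure D2:**
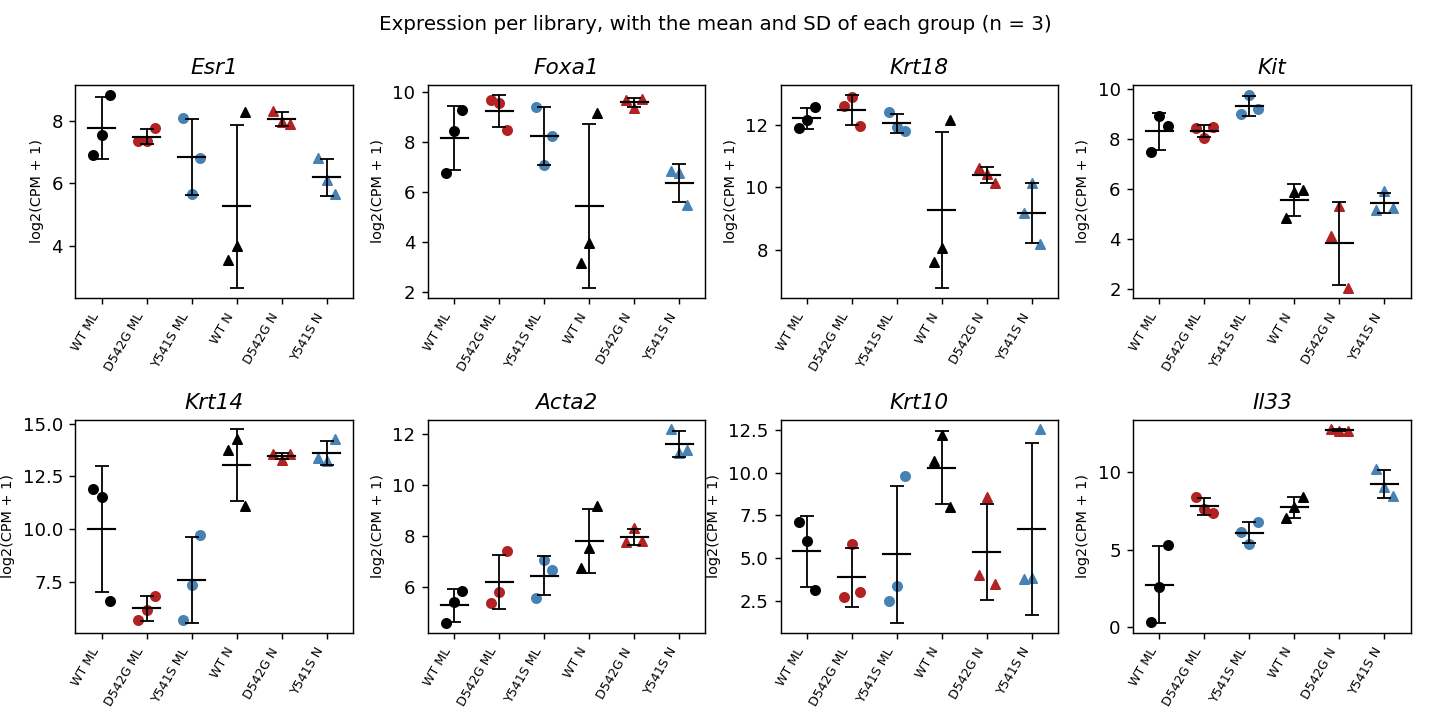
Expression (log2 of CPM + 1, vertical axis) of 8 genes in each of the 18 libraries (points), with the mean and SD of each group of 3. Kit is lower in N than in ML libraries of every genotype, Il33 is highest in D542G N, and Esr1, Foxa1 and Krt18 in WT N spread widely because WT N 3 stands apart from the other 2.

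Signalling and stress genes also moved between the gates. Immediate early genes rose for 11 of 20 and fell for none, with Egr2 at 2.62 ± 0.24, Myc at 1.82 ± 0.19 and Fosl1 at 2.52 ± 0.48. Genes of the androgen and glucocorticoid list rose for 7 of 13, led by the metallothioneins Mt1 (3.26 ± 0.34) and Mt2 (3.76 ± 0.44). Of Wnt targets 5 of 13 rose, among them the receptor Lgr5 (4.60 ± 0.57) and Apcdd1 (3.04 ± 0.61). Notch ligands Dll1 (4.95 ± 0.44), Jag2 (4.84 ± 0.78) and Jag1 (1.72 ± 0.21) rose and the receptor Notch3 fell (−1.92 ± 0.23), for 3 of 14 list members up and 2 down. Of TGF-β and BMP genes 8 of 18 rose, with Id1 at 2.06 ± 0.28 and Bmp2 at 2.96 ± 0.56, and 3 fell. Growth factor receptors rose for 4 of 17, with Fgfr3 at 2.54 ± 0.27, and fell for 5, with Erbb4 at −3.34 ± 0.40. Interferon-responsive genes fell for 11 of 20, with Oas1a at −1.63 ± 0.35 and Bst2 at −1.32 ± 0.26, and major histocompatibility class I genes fell for 6 of 10, with Psmb8 at −1.19 ± 0.20, while Nlrc5 rose (1.09 ± 0.27). NF-κB and inflammatory genes rose for 3 of 19, with Icam1 at 2.88 ± 0.19, and fell for 5, with Tnfaip2 at −3.68 ± 0.37. Adjusted over the list alone, 12 interferon genes fell, 9 TGF-β and BMP genes rose and 4 fell, 5 growth factor receptors rose and 5 fell, 3 Notch genes rose and 3 fell, and the counts of the other lists here were the same. Of these lists none was called as a set (adjusted p ≥ 0.426 with an estimated correlation). The median, mean and test of a list differed in sign for Notch genes (−0.39, 0.16, up), growth factor receptors (0.40, 0.04, down) and inflammatory genes (0.09, −0.40, down).

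Milk and alveolar genes fell for 9 of 19, among them Ltf (−3.81 ± 0.37), Lcn2 (−3.25 ± 0.38) and Mfge8 (−2.74 ± 0.22). Their sum was 40303 CPM in Y541S N 2, above every ML library but Y541S ML 2 (46466 CPM), and 1183 to 2154 CPM in the other N libraries. Secretory and ciliary genes fell for 7 of 12, with the mucin Muc4 at −4.41 ± 0.91 and Clu at −2.52 ± 0.26, and rose for 2, with Slpi at 3.49 ± 0.51 and Foxj1 at 2.21 ± 0.32. Genes of the p53 pathway rose for 5 of 17, among them the cell cycle inhibitors Cdkn1a (1.72 ± 0.39) and Cdkn1c (2.07 ± 0.25), and fell for 2. Of 24 cell cycle genes 1 was called (Aurka, −0.91 ± 0.30, not called adjusted over the list alone), a call lost without any 1 library other than WT ML 2, WT N 3, D542G ML 3, D542G N 1, Y541S ML 2 and Y541S N 2 (up to 0.0815). Heat shock genes rose for 3 of 12 and fell for 2, unfolded protein response genes rose for 2 of 18 and fell for 2, and glycolysis and hypoxia genes rose for 3 of 19 and fell for 5. Oxidative phosphorylation genes fell for 5 of 23, cholesterol synthesis genes for 4 of 19, fatty acid synthesis genes for 4 of 18 with Fads2 at −2.51 ± 0.28, and class II genes for 1 of 7, and none of these rose. Adjusted over the list alone, 8 secretory and ciliary genes and 3 fatty acid genes fell, 4 glycolysis and hypoxia genes rose and 7 fell, and the counts not mentioned were the same. None of these lists was called as a set (adjusted p ≥ 0.426 with an estimated correlation), and that of the unfolded protein response had a median of −0.11 and a mean of 0.00, with the test down.

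Genes that mark other cell types were read as a check on what the gates held. Endothelial genes rose for 8 of 12, among them Kdr (1.67 ± 0.43) and Pecam1 (1.18 ± 0.31), and Vwf fell (−1.47 ± 0.28). The nerve growth factor receptor Ngfr, on the Schwann and neural list, was the 1 of 7 members called, at 0 in all D542G ML libraries and at least 78.0-fold higher in N by mean CPM with the floor there. Of pericyte genes Mcam (2.63 ± 0.21) and Cspg4 (2.76 ± 0.59) rose and Notch3 fell, of 8. Fibroblast genes rose for 3 of 12, adipocyte genes for 3 of 8, erythroid genes for 2 of 4 and T and natural killer cell genes for 1 of 11 (Trbc2, 2.64 ± 0.37). Mast cell and neutrophil genes rose for 3 of 6, with Cma1 at 4.27 ± 0.90 and Tpsb2 at 3.88 ± 0.85. B and plasma cell genes fell for 3 of 7 and macrophage and dendritic genes for 1 of 13, and none of 8 skeletal muscle genes was called by edgeR. Adjusted over the list alone, 11 endothelial, 6 adipocyte, 4 erythroid and 4 mast cell and neutrophil genes rose, no macrophage gene was called, and the other counts were the same. None of these lists was called as a set (adjusted p ≥ 0.462 with an estimated correlation), and that of T and natural killer cells had a median of 0.13 and a mean of −0.12, with the test up. Of the lists chosen after the data were seen, hair follicle keratins fell for 9 of 11, immunoglobulin genes for 7 of 7, and epidermal genes rose for 1 of 9. Summed hair follicle keratins reached 6223, 1286 and 4054 CPM in WT ML 1, WT ML 2 and Y541S ML 3 and at most 151 CPM in any other library.

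Over all 18298 genes tested, edgeR's quasi-likelihood test called 5021 between the gates over the 3 genotypes, 2532 higher and 2489 lower in N. Of these, 3563 (71.0%) kept their call with each of the 18 libraries left out in turn. Genes at least partly inside another gene, and genes with close paralogs such as keratins and Serpinb members, are less certain than others.

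In WT mice N was compared with ML libraries after the same antagonist treatment. Neither untreated WT tissue nor the number of such cells in it was measured. Esr1 stood at −1.19 ± 0.96 (adjusted p = 0.501), at −2.63 ± 0.64 in the paired fit (0.0517), at −4.30 ± 0.74 without WT N 3 (0.00204) and at −3.86 by limma-voom (0.000674). Over the alternatives the adjusted p was 0.000674 to 0.848. Mmp2 (6.01 ± 0.69), Axl (3.27 ± 0.57), Sparc (3.17 ± 0.53), the Notch ligand Dll1 (4.56 ± 0.75), Myc (1.89 ± 0.33) and Icam1 (1.96 ± 0.31) rose in WT N cells. The luminal progenitor genes Lurap1l (−2.52 ± 0.29) and Hey1 (−3.96 ± 0.72), the milk fat globule gene Mfge8 (−3.10 ± 0.39), the cytokine Lif (−2.85 ± 0.46) and the receptor kinase Erbb4 (−5.09 ± 0.76) fell. Each of these 11 genes had adjusted p ≤ 0.0104, lay beyond the ML median in all 3 N libraries, and kept its call with each library left out in turn. Of luminal progenitor genes 6 of 15 fell (9 adjusted over the list alone), including Kit (−2.81 ± 0.66) and Elf5 (−3.77 ± 0.98). Of 17 basal genes 3 rose (10 adjusted over the list alone), and of 17 mesenchymal genes 5 (6). Krt14 stood at 2.36 ± 1.10 (adjusted p = 0.229), called in the paired fit at 3.01 (0.0415), and Krt5 at 2.78 ± 1.39 (0.263). No list was called as a set with an estimated correlation (adjusted p = 0.124 for the basal, the mesenchymal and the luminal progenitor list). In the paired fit the keratinocyte list was called (0.0356, against 0.679), and the summed epidermal genes stood at 1147 CPM or more in each WT N library and at 43.9 to 1111 CPM in WT ML.

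By size, the largest WT increases were those of Slc6a2 (9.60 ± 1.93), Gpha2 (7.97 ± 1.96), Dlk2 (7.67 ± 1.53), Adam28 (6.45 ± 1.46) and Cdh4 (6.34 ± 1.47). Adam28 had 213 counts in N and 2 in ML, a ratio of 105 (95% counting interval 28.6 to 869). It stood at 0.0252, 0.569 and 4.69 CPM in WT N 1 to 3 and at up to 0.0277 CPM in WT ML, so WT N 1 lay within the ML range. The largest decreases were those of Erbb4, Spns3 (−4.77 ± 1.04), the chloride channel gene Clic6 (−4.60 ± 0.77), Ppp1r9a (−4.26 ± 0.69) and Chst9 (−4.04 ± 0.94). Erbb4, Clic6 and Ppp1r9a kept their calls with each library left out. Slc6a2 lost its call without WT ML 1 or 3 (up to 0.0637), Dlk2 without WT ML 1 (adjusted p 0.0631), Adam28 without any WT ML library (up to 0.0922), Gpha2 without any WT ML library, WT N 1 or 2, D542G ML 1 or 2 or D542G N 3 (up to 0.108), Cdh4 without WT ML 2 or 3 or WT N 1 or 2 (up to 0.106), Spns3 without WT ML 1 or 2 or WT N 1 or 2 (up to 0.101) and Chst9 without WT ML 1 or 2 or WT N 1 or 2 (up to 0.133). In the paired fit Adam28 (adjusted p = 0.0749) and Chst9 (0.0592) were not called, and Gata3 (0.0267) and Epcam (0.0204) were. Kit lost its call without WT ML 2 or 3 or WT N 1 or 2 (up to 0.136), Elf5 without any 1 library other than D542G N 2, D542G N 3, Y541S ML 2, Y541S N 1, Y541S N 2 and Y541S N 3 (up to 0.16) and Itga6 (1.70 ± 0.35) without any WT ML library or WT N 1 or 2 (up to 0.0739). In WT edgeR with all libraries called no further gene from the fixed set of hormone, luminal and basal genes, with Greb1 at 0.76 ± 0.46, Prlr at −1.52 ± 0.83 and Krt18 at −1.51 ± 0.86 (−2.69 and −3.09 in the paired fit, adjusted p = 0.0759 and 0.0625).

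The test called 646 genes in WT, 392 higher and 254 lower in N. The count was 284, 239 and 276 without WT ML 1, 2 and 3, 183 and 200 without WT N 1 and 2, and 3045 without WT N 3. Of the 646 genes, 113 (17.5%) kept their call with each of the 18 libraries left out. With only the 6 WT libraries in the model 1 gene was called, Atp6v1b1, named after its values were seen.

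In D542G mice Esr1 did not differ detectably between the gates (0.56 ± 0.95, adjusted p = 0.774). Krt14 rose by 7.18 ± 1.37, the squamous keratin Krt6a by 4.50 ± 0.90, and Axl (4.99 ± 0.62) and Mmp2 (3.42 ± 0.61) rose as well. Among estrogen-responsive genes Igfbp4 (4.81 ± 0.69), Rerg (3.82 ± 0.45), Myb (3.89 ± 0.80) and the corepressor gene Nrip1 (1.22 ± 0.18) rose, and Ccnd1 fell (−2.84 ± 0.40). Kit (−4.04 ± 0.69), Aldh1a3 (−4.50 ± 0.68), Elf5 (−5.07 ± 1.05) and Muc1 (−5.31 ± 0.69) fell, as did the class I genes H2-K1 (−1.47 ± 0.29) and Psmb8 (−1.94 ± 0.35). All of these had adjusted p ≤ 0.00842 and kept their call with each library left out. Basal genes rose for 7 of 17 (13 adjusted over the list alone), keratinocyte genes for 3 (5) and mesenchymal genes for 4 (7) of 17. Luminal progenitor genes fell for 7 of 15 (10) and pan-luminal genes for 3 of 15 (5). Of the 7 contractile genes on the basal list none was called by edgeR, with log2 fold changes of 0.02 to 2.65, while 5 of 6 keratin and adhesion genes were, with 3.89 to 7.18. This grouping was chosen after the data were seen and leaves out Igfbp2, Sparc, Lgr6 and Sncg. In WT 1 of the 7 contractile genes was called, with 0.98 to 3.22. Of the 6 keratin and adhesion genes 1 was called in WT, with 0.99 to 5.53. No list was called as a set (adjusted p = 0.118 for the basal list with an estimated correlation).

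The largest D542G increases were those of Slc6a2 (8.81 ± 1.83), the p53 family gene Trp73 (8.27 ± 1.58), Gpha2 (7.80 ± 2.18), Dlk2 (7.76 ± 1.54) and Hs6st2 (7.50 ± 1.78). Gpha2 had 583 counts in N and 2 in ML, a ratio of 284 (95% counting interval 78.2 to 2348), and stood at 0.4, 9.61 and 1.88 CPM in D542G N 1 to 3. The largest decreases were those of Unc5cl (−7.06 ± 1.81), Apof (−6.36 ± 1.83), Calca (−6.35 ± 1.86), Upk2 (−5.81 ± 1.46) and Tmprss6 (−5.78 ± 1.55). Slc6a2, Trp73 and Dlk2 kept their calls with each library left out. Gpha2 lost its call without any D542G ML library or D542G N 2 or 3 (up to 0.132), Hs6st2 without D542G ML 1 or 2 (up to 0.0676), Unc5cl without D542G ML 1 or any D542G N library (up to 0.0955), Upk2 without D542G ML 1 or 2 or any D542G N library (up to 0.0819), Tmprss6 without D542G ML 2 or 3 or any D542G N library (up to 0.12), Apof without any 1 library other than WT ML 1, WT N 1, WT N 2, WT N 3, D542G N 2, Y541S N 2 and Y541S N 3 (up to 0.133) and Calca without any 1 library other than WT ML 1, WT ML 3, WT N 3, Y541S ML 1, Y541S ML 3, Y541S N 1 and Y541S N 3 (up to 0.145). Greb1 rose (1.94 ± 0.47), with its call lost without D542G ML 1 or 2 or D542G N 2 (up to 0.0913), and Itga6 rose (1.45 ± 0.34), lost without D542G ML 1 or 2 or D542G N 3 (up to 0.0843). Gata3 fell (−1.85 ± 0.40), lost without D542G N 1 (adjusted p 0.0523), and Prlr fell (−3.38 ± 0.90), lost without D542G ML 1 or 2 or any D542G N library (up to 0.118). Krt5 rose (5.84 ± 1.60), lost without any D542G ML library or any D542G N library (up to 0.13). Krt8 stood at −2.30 ± 0.84 (adjusted p = 0.101, 0.0453 in the paired fit), Foxa1 at 0.26 ± 1.11 and Pgr at 0.06 ± 1.03, and the rest of the fixed set was not called.

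In D542G the test called 1684 genes, 862 higher and 822 lower in N. The count was 755 and 770 without D542G ML 1 and 2, 806, 932 and 732 without D542G N 1, 2 and 3, and 2605 without WT N 3, which shares in the estimate of dispersion. Of the 1684 genes, 547 (32.5%) kept their call in all 18 fits. With only the 6 D542G libraries in the model 3373 were called. Mitochondrial genes held 0.313 to 0.501% of counts in D542G N and 0.509 to 1.03% in D542G ML. Malat1 held 0.0852 to 0.165% and 0.189 to 0.908%, and ribosomal protein genes 0.354 to 0.444% and 0.263 to 0.278%, in the same order. Whether these shares bear on the calls was not tested.

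In Y541S mice Esr1 stood at −0.92 ± 0.96 between the gates (adjusted p = 0.633). Acta2 (5.13 ± 0.75), Oxtr (5.61 ± 0.84), Cnn1 (5.87 ± 1.0), Tagln (3.92 ± 0.50) and Sparc (4.52 ± 0.56) rose, with Mmp2 (5.87 ± 0.68), Vim (3.36 ± 0.52), Prrx1 (4.24 ± 0.81) and the adhesion gene Mcam (3.96 ± 0.39). Acta2 stood at 3251 ± 1209 CPM in Y541S N libraries, against 289 ± 256 in WT N and 251 ± 58.3 in D542G N. Pericyte genes, Mcam among them, summed to 380 ± 62.1 CPM in Y541S N, 105 ± 30.3 in Y541S ML, 136 ± 14.2 in WT N and 112 ± 1.83 in D542G N. Endothelial genes summed to 574 ± 355 CPM in Y541S N, 283 ± 53.3 in Y541S ML, 237 ± 39.2 in WT N and 196 ± 52.8 in D542G N. Greb1 rose (2.82 ± 0.49), and Kit (−3.93 ± 0.69), Aldh1a3 (−4.19 ± 0.67) and Ccnd1 (−2.92 ± 0.40) fell. Each of these 13 genes had adjusted p ≤ 0.00593, lay beyond the ML median in all 3 N libraries, and kept its call with each library left out. Basal genes rose for 11 of 17 (15 adjusted over the list alone, where 1 fell) and the set was called (adjusted p = 0.00921 with an estimated correlation, 0.0595 in the paired fit). Mesenchymal genes rose for 5 of 17 (8) and were called as a set (0.0393, paired 0.0770). Pan-luminal genes fell for 5 of 15 (11) and luminal progenitor genes for 5 of 15 (8), and neither set was called (0.0655 and 0.315 with an estimated correlation). Epidermal genes summed to 14912 CPM in Y541S N 3 and to 58.7 CPM or less in the other 2 N libraries.

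The largest Y541S increases were those of Vsnl1 (7.65 ± 0.63), Xkr4 (7.55 ± 1.29), the collagens Col7a1 (6.96 ± 1.14) and Col14a1 (6.73 ± 0.98) and the Wnt-pathway receptor Lgr5 (6.72 ± 1.08), all kept with each library left out. The largest decreases were those of Ctse (−4.37 ± 1.21), Hap1 (−4.28 ± 1.01), Aldh1a3, Alox15 (−4.14 ± 0.88) and Scml4 (−4.10 ± 0.70). Aldh1a3 and Scml4 kept their calls, while Hap1 lost its call without Y541S ML 1 or Y541S N 1 or 3 (up to 0.0837), Alox15 without Y541S N 1 (adjusted p 0.0519) and Ctse without any 1 library other than WT N 1, WT N 2, WT N 3 and Y541S ML 2 (up to 0.128). Krt14 rose (5.24 ± 1.25), a call lost without Y541S ML 1 or 2 (up to 0.0867), and Itga6 rose (1.52 ± 0.34), lost without Y541S ML 2 or 3 or Y541S N 1 (up to 0.0716). Epcam fell (−1.83 ± 0.40), lost without Y541S N 1 or 3 (up to 0.0611), and Prlr fell (−3.25 ± 0.89), lost without any 1 library other than WT ML 1, WT ML 3, WT N 1, WT N 2, WT N 3 and Y541S ML 2 (up to 0.152). Krt5 (5.05 ± 1.54), Elf5 (−2.38 ± 0.92), Gata3 (−0.92 ± 0.39) and Krt18 (−2.70 ± 0.90) were not called without pairs and were called with them (adjusted p = 0.0103, 0.0237, 0.0495 and 0.0395), and the rest of the fixed set was not called.

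The test called 1272 genes in Y541S, 773 higher and 499 lower in N. The count was 598 and 690 without Y541S ML 1 and 2, 622 without Y541S N 1, and 2091 without WT N 3. Of the 1272 genes, 457 (35.9%) kept their call in all 18 fits.

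**Figure D3:**
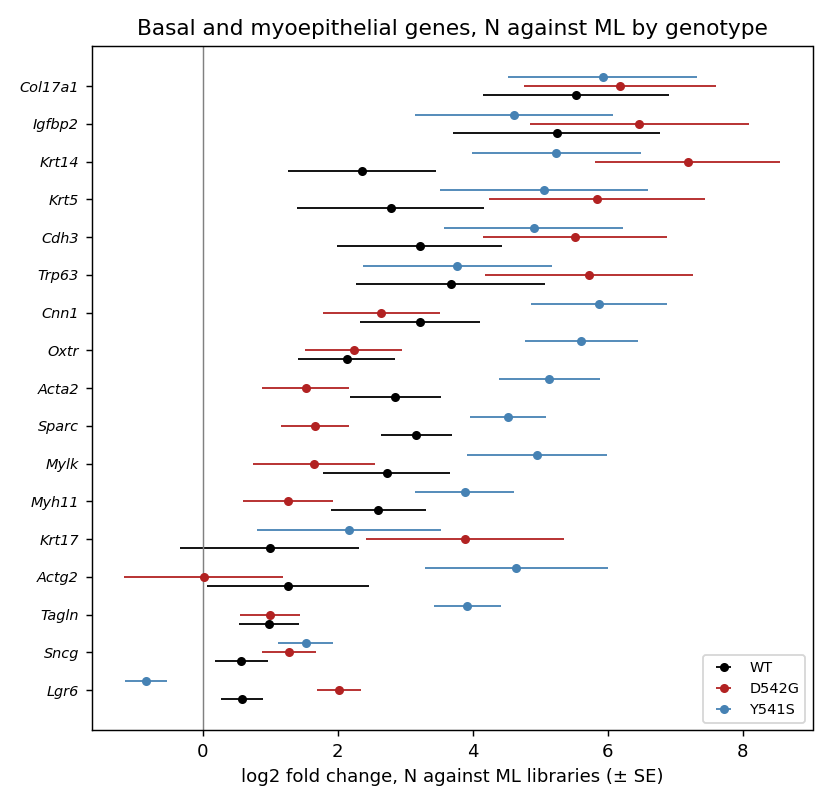
Log2 fold change of N against ML ± standard error (horizontal axis) for the 17 measured genes of the basal and myoepithelial list in WT, D542G and Y541S mice, from 3 libraries per gate and genotype. In D542G the 7 contractile genes lie between 0.02 and 2.65, below the keratin and adhesion genes at 3.89 to 7.18. In WT the same groups, chosen after the data were seen, lie at 0.98 to 3.22 and at 0.99 to 5.53.

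Whether the difference seen in the mutants was also present in WT mice given the same antagonist was read from the genes called with the same sign in both mutants. There were 611 such genes, 379 higher and 232 lower in N, against 36.4 and 22.4 if the lists were independent. In WT, 590 of them (96.6%, exact 95% confidence interval 94.8 to 97.9%) had the same sign, and 254 were also called. Genes are not independent replicates, so the interval covers counting only. Their median change in the shared direction was 1.38 on the log2 scale in WT, 2.36 in D542G and 2.31 in Y541S, where the mutant values come from genes chosen for being called in them. The group means of the 3 genotype comparisons share no library. All 18 libraries share in the estimate of dispersion, however, so the lists of called genes are not fully independent. Of the 646 genes called in WT, 605 (93.7%) had the same sign in D542G and 615 (95.2%) in Y541S. Across all genes the fold changes of WT correlated with those of D542G at r = 0.43 and of Y541S at r = 0.47, and those of the mutants with each other at r = 0.48. Kit, Aldh1a3, Mmp2, Axl, Dll1, Icam1 and Egr2 were called with the same sign in each genotype, Icam1 at 1.96 ± 0.31, 4.15 ± 0.34 and 2.52 ± 0.32 in WT, D542G and Y541S.

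N cells of D542G mice were compared with N cells of WT mice. Esr1 stood at 1.27 ± 0.96 (adjusted p = 0.521) at 4.38 ± 0.75 without WT N 3 (0.00521) and at 4.19 by limma-voom (0.000488). Over the alternatives the adjusted p was 0.000488 to 0.788. Higher in D542G N were Ltbp1, which binds latent TGF-β (3.56 ± 0.45, 305 ± 36.3 against 25.8 ± 12.6 CPM), Rerg (3.10 ± 0.44), Icam1 (2.10 ± 0.31), Nrip1 (1.40 ± 0.18), Lurap1l (1.68 ± 0.28) and Tgfb1 (1.29 ± 0.16). All 6 had adjusted p ≤ 0.0076, lay above the WT N median in 3 of 3 libraries, and kept their calls with each library left out. Of TGF-β and BMP genes 3 of 18 rose (6 adjusted over the list alone, where 1 fell), and of estrogen-responsive genes 3 of 22. Class I genes fell for 2 of 10 (6 adjusted over the list alone), with H2-K1 at −1.65 ± 0.29, a call lost without D542G N 1 (adjusted p 0.0632). Cholesterol synthesis genes fell for 2 of 19 (12 adjusted over the list alone), with the enzyme Sqle at −2.77 ± 0.61, lost without WT N 2 or D542G N 1 or 3 (up to 0.129). No list was called as a set (adjusted p = 0.224, 0.546, 0.546 and 0.794 with an estimated correlation, in the order given). Epidermal genes stood at 70.4 to 1230 CPM in D542G N and 1147 to 14776 CPM in WT N, and Il33, an alarmin of barrier tissues, at 6402 ± 291 and 222 ± 98 CPM.

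The homeobox gene En2 (ENSMUSG00000039095, chromosome 5 28165694–28172166) was at 57.5 ± 19.8 CPM in D542G N and at 0 in the 3 WT N libraries, at least 760-fold higher against a floor of 3 counts per library (0.0757 CPM). The other largest increases were those of Crabp1 (5.01 ± 1.24), Olfml2a (4.87 ± 0.90), Il33 (ENSMUSG00000024810, chromosome 19 29925114–29960718; 4.85 ± 1.12) and Adam28 (4.76 ± 1.15). The largest decreases were those of Atp8a2 (−5.24 ± 1.11), Adgrl3 (−4.28 ± 0.72), Dlg2 (−3.73 ± 0.91), Upb1 (−3.71 ± 0.79) and Hlf (−3.59 ± 0.86). None of these 10 kept its call with each library left out. Olfml2a lost it without WT N 1 or 2 (up to 0.0699), Adgrl3 without D542G N 1 (adjusted p 0.0563), Atp8a2 without WT N 1 or 2 or D542G N 1 or 3 (up to 0.129) and Upb1 without WT N 1 or 2 or D542G N 1 or 3 (up to 0.129). En2 lost it without WT N 1 or 2, D542G ML 1 or 2 or any D542G N library (up to 0.109), Il33 without WT N 1 or 2, D542G ML 1 or 2, any D542G N library or Y541S ML 1 (up to 0.127) and Crabp1 without any 1 library other than WT ML 1, WT ML 2, WT ML 3 and Y541S N 3 (up to 0.141). For Adam28 it was lost without any 1 library other than WT ML 3, WT N 3, Y541S ML 1, Y541S N 1 and Y541S N 3 (up to 0.141), for Dlg2 without any 1 library other than WT N 3, D542G N 2, Y541S ML 2, Y541S N 1, Y541S N 2 and Y541S N 3 (up to 0.177) and for Hlf without any 1 library other than WT ML 1, WT N 3, D542G N 2, Y541S ML 2, Y541S N 1 and Y541S N 3 (up to 0.175). With the library number as a block Crabp1 (adjusted p = 0.0610), Il33 (0.0532) and Dlg2 (0.0633) were not called.

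The test called 444 genes, 294 higher and 150 lower in D542G N. The count was 96, 197 and 113 without D542G N 1, 2 and 3, 156 and 138 without WT N 1 and 2, and 1408 without WT N 3. It was 101 with only the 6 libraries compared in the model, 277 with no filter on low counts, and 96 with an epidermal covariate chosen after the data were seen. Of the 444 genes, 74 (16.7%) kept their call with each library left out.

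N cells of Y541S mice were compared with N cells of WT mice in the same way. Esr1 stood at −0.54 ± 0.95 (adjusted p = 0.854), at 0.11 ± 1.04 with the library number as a block (0.985) at 2.58 ± 0.68 without WT N 3 (0.0590), at 2.50 by limma-voom (0.0370) and at 2.83 ± 0.64 without 5 libraries in doubt (0.0195). Over the alternatives the adjusted p was 0.0195 to 0.985. The secreted factor Serpinf1 (ENSMUSG00000000753; 4.95 ± 0.53, 224 ± 103 against 7.24 ± 3.47 CPM), Tagln (3.22 ± 0.48), Mcam (2.67 ± 0.37), the peptide hormone gene Cck (4.58 ± 0.62) and Lurap1l (1.86 ± 0.28) were higher in Y541S N, and the insulin-degrading enzyme Ide was lower (−1.89 ± 0.26). These 6 genes had adjusted p ≤ 0.00622, lay beyond the WT N median in 3 of 3 libraries, and kept their calls with each library left out. Of basal genes 3 of 17 rose (8 adjusted over the list alone), with Acta2 at 3.49 ± 0.69, a call lost without WT N 1 or 2 or Y541S N 1 or 2 (up to 0.117), and Oxtr at 3.67 ± 0.76, lost without WT N 1 or 2, any D542G N library or Y541S N 1 or 2 (up to 0.131). Luminal progenitor genes rose for 3 of 15 (5). Neither set was called (adjusted p = 0.463 for each with an estimated correlation). Epidermal genes were at 7417, 14776 and 1147 CPM in WT N 1 to 3, at 58.7 CPM or less in Y541S N 1 and 2 and at 14912 CPM in Y541S N 3, the library closest to WT N 2.

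By size, Pamr1 (7.20 ± 1.18), Serpinf1, Itga8 (4.81 ± 0.90), Cck and the glucose transporter Slc2a4 (4.38 ± 0.89) rose most. Ephx2 (−2.40 ± 0.46), Dennd1c (−2.24 ± 0.44), Ide, Elovl7 (−1.70 ± 0.33) and Btaf1 (−1.49 ± 0.32) fell most. Pamr1 lost its call without WT N 2 (adjusted p 0.0606), Dennd1c without WT N 2 or Y541S N 1 or 2 (up to 0.108) and Btaf1 without WT ML 2, WT N 1 or 2, any D542G N library, Y541S ML 3 or Y541S N 1 or 2 (up to 0.158). Itga8 lost it without WT N 1 or 2 or Y541S N 1 or 2 (up to 0.0767), and Slc2a4, Ephx2 and Elovl7 without the same 4 libraries (up to 0.110, 0.114 and 0.122). With the library number as a block Slc2a4 was not called (0.0570). The test called 208 genes, 187 higher and 21 lower in Y541S N, and 134 with the block. The count was 48, 64 and 699 without Y541S N 1, 2 and 3, and 55, 60 and 535 without WT N 1, 2 and 3. It was 0 by edgeR with only the 6 libraries compared in the model. Of the 208 genes, 34 (16.3%) kept their call with each library left out.

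The N cells of the 2 mutants were compared with each other. Esr1 stood at 1.80 ± 0.98 (adjusted p = 0.432), called with only the 6 libraries compared in the model (1.80 ± 0.31, 0.0325) and in no other alternative (up to 0.637). Tagln (−3.30 ± 0.48) and Serpinf1 (−4.55 ± 0.52) were lower in D542G N, and the scavenger receptor Scara5 (3.09 ± 0.40) and Nrip1 (1.32 ± 0.18) were higher, each in 3 of 3 libraries against the Y541S N median, with adjusted p ≤ 0.00344, and kept with each library left out. Of basal genes 4 of 17 were lower and 1 higher in D542G N (8 and 1 adjusted over the list alone), with Sparc at −3.18 ± 0.53, a call lost without D542G N 1 (adjusted p 0.0661). Mesenchymal genes were lower for 3 of 17 (4) and fatty acid synthesis genes for 2 of 18 (4). Of 19 milk genes none was called over all genes and 17 were lower adjusted over the list alone, and those genes summed to 40303 CPM in Y541S N 2 and to 1183 to 2154 CPM in the other N libraries. No list was called as a set (adjusted p = 0.299 for the basal, 0.452 for the mesenchymal, 0.299 for the fatty acid and 0.457 for the milk list with an estimated correlation).

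Prune2 (3.80 ± 0.76), Ces2g (3.79 ± 0.89), Sel1l3 (3.59 ± 0.83), Kcns3 (3.32 ± 0.65) and Scara5 were highest in D542G N relative to Y541S N. Colgalt2 (−5.44 ± 0.87), Postn (−4.65 ± 0.81), Serpinf1, Pamr1 (−4.42 ± 1.03) and Lgr5 (−4.42 ± 0.97) were lowest. Colgalt2 lost its call without D542G N 1 or 3 (up to 0.0581), Postn without D542G N 1 or 3 (up to 0.0815), Prune2 without any D542G N library or Y541S N 2 or 3 (up to 0.107) and Kcns3 without D542G N 1 or 2 or Y541S N 2 or 3 (up to 0.0995). Lgr5 lost it without WT ML 2, D542G ML 1, any D542G N library or Y541S N 1 or 2 (up to 0.185), Pamr1 without any 1 library other than WT ML 1, WT ML 3, WT N 1, WT N 3, D542G ML 3 and Y541S N 3 (up to 0.208), Ces2g without any 1 library other than WT ML 3, WT N 1, WT N 3 and Y541S ML 2 (up to 0.179) and Sel1l3 without any 1 library other than WT ML 1, WT ML 2, WT N 1, WT N 2 and WT N 3 (up to 0.143). With the library number as a block Ces2g (0.0783), Sel1l3 (0.0677), Pamr1 (0.0878) and Lgr5 (0.0654) were not called. The test called 261 genes, 77 higher and 184 lower in D542G N, and 523 with only the 6 libraries compared in the model. The count was 57, 110 and 62 without D542G N 1, 2 and 3, 172 and 107 without Y541S N 1 and 2, and 511 without WT N 3. Of the 261 genes, 49 (18.8%) kept their call with each library left out.

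In the ML gate the genotypes were compared to ask whether the mutations change mature luminal cells under the antagonist. Esr1 stood at −0.49 ± 0.95 in D542G against WT, −0.81 ± 0.95 in Y541S against WT and 0.32 ± 0.95 in D542G against Y541S (adjusted p ≥ 0.926). In that order the alternatives gave −1.34 to 0.24, −1.65 to −0.08 and −0.08 to 1.16, and none called it. EdgeR called 0 genes between D542G and WT, 0 between Y541S and WT and 0 between the mutants, with 1129, 1012 and 886 genes at an unadjusted p under 0.05. DESeq2 called 110, 51 and 63, and limma-voom with quality weights 93, 3 (Tnmd, Gabrg3 and Gm42031) and 10. In edgeR the counts for D542G and for Y541S against WT were each 1 when WT ML 1, 2 or 3 was left out, and the gene was Gpr27, Slc14a1 and Tmem182 in that order in both. These 6 genes, named since the counts are small, were chosen after their values were seen. Simulated genes that changed 4-fold were recovered for 44%, 54% and 44% of 50 genes in these comparisons, so changes of that size can be missed. No list was called as a set (none of 39 in any of the 3 comparisons with an estimated correlation). The ML libraries differed in hair follicle keratins and immunoglobulin genes, which summed to 2198, 5270 and 6212 CPM in WT ML 1, WT ML 2 and Y541S ML 2 and to at most 516 CPM in the other libraries.

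Last, the change from ML to N was compared between each mutant and WT. For Esr1 the difference was 1.76 ± 1.35 for D542G (adjusted p = 0.691) and 0.28 ± 1.34 for Y541S (0.986). In the paired fit these were 3.19 ± 0.85 (0.206) and 1.95 ± 0.85 (0.581), and without WT N 3 they were 4.87 ± 0.89 (0.0254) and 3.39 ± 0.86 (0.112). Limma-voom gave 4.51 (0.00430) and 3.33 (0.0598). The fit without 5 libraries in doubt, in which WT ML 3 is the only WT ML library, gave 5.74 and 4.35. Over the alternatives the adjusted p was at most 0.834 and 1.0. For D542G the test called 20 genes, 19 with a log2 fold change of N against ML that was higher in D542G than in WT. Rerg changed by 3.82 ± 0.45 between the gates in D542G and by −0.20 ± 0.40 in WT, a difference of 4.03 ± 0.59 (adjusted p = 0.0174). For Ltbp1 the values were 1.22 ± 0.41 and −2.77 ± 0.44, with a difference of 3.99 ± 0.60 (adjusted p = 0.0187), and for Sncaip the difference was 4.44 ± 0.68 and for Chp1 −1.53 ± 0.26. TGF-β and BMP genes differed as a set (median difference 1.30 on the log2 scale over 18 genes, adjusted p = 0.0234 with an estimated correlation), with 1 of 18 called over all genes and 9 adjusted over the list alone, and 0.302 in the paired fit. Krt14 and Acta2, called in 1 comparison and not in another, had differences of 4.82 ± 1.55 (adjusted p = 0.291) and −1.33 ± 0.90 (0.633) between D542G and WT, and of 2.87 ± 1.5 (0.652) and 2.28 ± 0.90 (0.538) between Y541S and WT. Rerg lost its call without D542G ML 1 or 2 or D542G N 1 (up to 0.0754), Ltbp1 without D542G ML 1 or 2 or D542G N 1 (up to 0.0754), Sncaip without WT N 1 or 2, D542G ML 1 or 2 or D542G N 1 (up to 0.0877) and Chp1 without any 1 library other than WT ML 3, WT N 3, Y541S ML 1, Y541S ML 2, Y541S N 1, Y541S N 2 and Y541S N 3 (up to 0.133). In the paired fit Sncaip (0.0902), Rerg (0.0503) and Chp1 (0.0864) were not called. The count of 20 was 3 and 5 without D542G ML 1 and 2, 6 and 13 without D542G N 1 and 3, 11 and 156 without WT N 2 and 3, and 34 without Y541S N 3. For Y541S edgeR called 0 genes, with 1538 at an unadjusted p under 0.05, DESeq2 called 185 and limma-voom 334, and the edgeR count was 38 without Y541S N 3 and 62 without WT N 3.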

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

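The tests of explanations and the counts over other splits of the samples in this part were chosen after the results they bear on were seen, while the interaction test was planned.

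The change from ML to N differed between D542G and WT for 20 genes by the interaction test, which is what marked them for a closer look. They include Sncaip (4.44 on the log2 scale), Rerg (4.03), Ltbp1 (3.99) and Chp1 (−1.53), of which only Ltbp1 was called in the paired fit (adjusted p = 0.0435). The TGF-β and BMP list differed as a set in the same test, with a median of 1.30, and was not called in the paired fit (adjusted p = 0.302). Of 100 splits drawn from the 200 that regroup the libraries between D542G and WT, 5 gave at least 20 genes, the real one included, and the highest of the others gave 201, so chance cannot be excluded by this count. These splits regroup N and ML libraries separately and so break pairs that the real split keeps, and the highest, which exchanged WT ML 3 with D542G ML 3, points with several times the real count to a structure of the samples. With whole pairs regrouped there are 10 splits, too few for a share under 0.05, and the real one gave 20 genes and the highest other 0. For Y541S all 100 splits gave a count of at least the real 0, with a highest other of 742, and with whole pairs all 10 did, with a highest other of 28.

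Between gates within a genotype, 3 against 3 libraries allow only 10 splits, too few for a share under 0.05. In WT 1 split, the real one, gave as many as 646 genes, and the highest other gave 450, when WT ML 2 and 3 were grouped with WT N 3. In D542G 1 split reached 1684 and the highest other gave 0, and in Y541S 1 split reached 1272 and the highest other gave 1. Splits that part all 3 pairs of equal number treat the pairs as the real one does, and the 3 others of that kind gave 0 in each genotype. They are too few to test chance, and they leave out the WT split with 450 genes. Over the 3 genotypes 1 of 100 splits drawn from 4000, the real one, reached 5021 genes, and the highest other gave 2056. With N and ML exchanged only within pairs 1 of 100 splits drawn from 256, the real one, reached it, and the highest other gave 1928. A share of 1 in 100 makes chance an unlikely source there but does not exclude it, and the pairs were read from these same data.

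Within the N gate 10 splits are again too few for a share under 0.05. D542G against WT gave 444 genes in 1 split and at most 1 in the others, and D542G against Y541S 261 in 1 split and 0 in the others. For Y541S against WT 2 of 10 splits gave at least 208 genes, and the higher of them, which exchanged WT N 3 and Y541S N 3, gave 1653. That count of several times the real one points to a structure of the samples. In the ML gate all 10 of 10 splits gave at least the real 0 genes, and the highest others gave 82 for D542G against WT, 36 for Y541S against WT and 1 for the mutants.

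The WT N 3 library lay between the N and the ML libraries. A wrong label on a mature luminal library is argued against: of the 611 genes called alike in both mutants, 38.6% lay inside the range of the ML libraries in WT N 3, against 61.4 to 89.2% for each ML library and 1.96 to 21.1% for the other N libraries. Over these genes, a mixture of the sorted mature luminal population with cells like those of WT N 1 and 2 is argued against too. The ML share it would need was 0.805 as a median over 132 genes higher in WT N 1 and 2 and 0.164 over 93 lower genes, a difference of 0.641 (bootstrap 95% interval 0.486 to 0.715) where a single share would give 0. The interval resamples genes, which are not independent replicates, and may be too narrow. Both gene sets were drawn from the 611, and the ML reference was the mean of the 3 WT ML libraries. Krt18, called in neither mutant, stood at 4583 CPM in WT N 3, inside the ML range of 3580 to 7638 CPM. Whether other genes, or WT ML 3 alone as the reference, give another share was not tested. A mixture with only a part of the luminal cells may remain, as may a biological difference between animals, and neither was tested.

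Basal keratin genes were higher in N than in ML libraries. As the whole source, cells of the differentiating epidermis are argued against in D542G, where 7 of 7 called basal genes were still called with the epidermal covariate (Krt1, Krt10 and Krtdap), and Krt10 stood at 15.2, 386 and 10.2 CPM in D542G N against Krt14 at 11350 ± 1248. In WT 1 of 3 was still called. The median fold of these 3 genes went from 3.17 to 3.30 and the median of their standard errors from 0.676 to 0.726, and since the covariate follows the WT N group, such cells and the N gate cannot be told apart in WT. In D542G the 7 contractile genes reached at most 2.65, while 6 keratin and adhesion genes lay at 3.89 to 7.18. In Y541S the same contractile genes lay at 3.88 to 5.87. In WT they lay at 0.98 to 3.22, and the keratin and adhesion genes at 0.99 to 5.53. Such folds also depend on the level of each gene in ML libraries, which was not tested. Whether myoepithelial cells were the whole source in D542G is therefore not decided. Undifferentiated cells of the epidermis or hair follicle, which these markers do not show, may be a source, since the keratin and adhesion genes (median 5.78) are shared by such cells and mammary basal cells, and the 2 cannot be told apart in D542G. An altered luminal state in the N gate may account for part of the pattern and was not tested.

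D542G N and WT N libraries differed. A difference in epidermal content may contribute: with the covariate the median fold of the 444 called genes went from 1.78 to 1.55 on the log2 scale and the median of their standard errors from 0.352 to 0.374. Of the 444 genes 93 were still called, and all 444 kept their sign. The covariate differs between these groups, so epidermal content and genotype cannot be told apart for these genes. WT N 3 alone as the source is argued against, since 1408 genes were called without it, 397 of them among the 444. The genotype, which the design names, stays open and was not tested apart from the epidermal content.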

How the results depend on the processing

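The epidermal covariate and the fit without 5 libraries were chosen after the data were seen, and the other alternatives before. Of the 164 results of named genes, none that was called reversed its sign under any alternative. The signs of other called genes were not checked under all alternatives. Some values not called in the main model did reverse, among them Esr1 in Y541S N against WT N. It stood at −0.54 in the main model, 2.50 by limma-voom (adjusted p = 0.0370) and 2.83 without the 5 libraries (0.0195). DESeq2 size factors in edgeR moved no count by over 1.5 times and moved the median of all genes by at most 0.04 on the log2 scale. Where a count moved, the cause was not tested, except that fits without libraries or with only some groups rest on fewer samples. Depth (34797778 to 49507144 counts) limits genes near the filter.

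For N against ML in WT (646 genes), the count was 2064 by the DESeq2 Wald test, 5167 by limma-voom with quality weights, 1 with only the groups compared, 231 with the epidermal covariate and 2594 without the 5 libraries. In D542G (1684) it was 3186, 5862 and 3373 by the first 3 of these and 3078 without the 5 libraries. In Y541S (1272) it was 2494 by DESeq2 and 2595 by limma-voom. Over the genotypes (5021) it was 7690 by limma-voom. For D542G against WT in N (444) it was 277 with no low-count filter, 1714 by DESeq2, 4096 by limma-voom, 101 with only the groups compared, 96 with the covariate and 2173 without the 5 libraries. For Y541S against WT in N (208) it was 1065, 1931, 0 with only the groups compared, 134 with the replicate block, 49 with the covariate and 2327 without the 5 libraries. For D542G against Y541S in N (261) it was 1140, 1221, 523 with only the groups compared and 741 without the 5 libraries. In ML the counts of 0 became 110, 51 and 63 by DESeq2 and 93, 3 and 10 by limma-voom. D542G against WT in ML had 1 gene with the covariate (Cxcl1), a gene chosen after its values were seen. The D542G interaction (20) was 404 by DESeq2, 1254 by limma-voom and 344 without the 5 libraries, and that of Y541S (0) was 185, 334 and 458. The share of mutant calls with the same sign in WT (96.6%) was 93.2% by limma-voom and 92.1% without the 5 libraries, where the WT sign rests on 1 WT ML library. DESeq2 gave no adjusted p for 143 to 1888 genes, depending on the contrast. A fit of only the groups compared could not be made for the mean over genotypes or the share. The counts without the 5 libraries for N against ML in WT and for the interactions rest on 1 WT ML library. They cannot show the spread within that group, and no conclusion is drawn from them.

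With the replicate block the counts were 900 in WT, 1955 in D542G, 1589 in Y541S and 4903 over the genotypes, 309, 134 and 192 between genotypes in N, 0, 0 and 0 in ML, and 15 and 0 for the interactions, with a share of 96.7%. The block changed 25 of 164 calls of named genes (16 lost, 9 gained) and the gene set calls given beside the results, and changed no other call of a gene or list that the text names.

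With each library left out in turn the count ranged from 183 to 3045 in WT, 732 to 2605 in D542G, 598 to 2091 in Y541S and 4134 to 6398 over the genotypes. In N it ranged from 96 to 1408, 48 to 699 and 57 to 511, in the order D542G against WT, Y541S against WT and the mutants. In ML it ranged from 0 to 1, 0 to 1 and 0 to 0, for the D542G interaction from 3 to 156 and for Y541S from 0 to 62. The share ranged from 92.5 to 99.4%. Over 164 results of named genes, leaving out a library ended the call in 365 cases and brought one in 31. It turned the sign of an uncalled value in 27 cases and kept both sign and call in 2529. Calls ended and were brought in 4 and 9 times by DESeq2, 12 and 29 by limma-voom, 32 and 7 with only the groups compared, 30 and 1 with the covariate, and 18 and 27 without the 5 libraries. No filter ended 8 and DESeq2 size factors 1. The tally without the 5 libraries includes comparisons that rest on 1 WT ML library.

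Camera with the preset correlation called 15, 18, 15 and 18 of 39 lists for N against ML in WT, D542G, Y541S and their mean, against 0, 0, 2 and 2 with an estimated correlation. It called 6, 14 and 11 in N, 10, 14 and 15 in ML and 12 and 4 for the interactions, against 0, 0, 0, 0, 0, 0, 1 and 0.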

Other observations

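The tests in this part are read as values, and the lists of hair follicle keratins and immunoglobulin genes were chosen after the data were seen.

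Several groups of genes were high in single libraries. Summed immunoglobulin genes reached 2198, 5270 and 6212 CPM in WT ML 1, WT ML 2 and Y541S ML 2, and 9.85 CPM in WT ML 3. Ighg1 was highest at 1524 CPM in Y541S ML 2 and Ighg2c at 1058 CPM in WT ML 2, and Ighg2c had a count in 7 of 9 ML and 0 of 9 N libraries. Hair follicle keratins reached 6223 CPM in WT ML 1 and 4054 CPM in Y541S ML 3 but only 1.72 CPM in WT ML 3. Milk genes were high in both gates of the same number in Y541S, with 46466 CPM in Y541S ML 2 and 40303 CPM in Y541S N 2. Csn2, the gene of β-casein, stood at 9321 and 17510 CPM there, and Wap, a whey protein gene, at 274 and 2617 CPM, while Csn2 stood at 155 CPM or less in every other library. Endothelial genes summed to 984 CPM in Y541S N 2 and to at most 375 CPM in any other library, and mast cell and neutrophil genes to 74.7 CPM there and at most 23.5 CPM elsewhere.

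Metallothionein 1 (Mt1) averaged 2294 ± 1111, 2933 ± 1449 and 2173 ± 384 CPM in WT, D542G and Y541S N libraries, against 459 ± 363, 159 ± 48.1 and 229.7 ± 80.6 in ML. Of the 20 genes with a different change in D542G, Pde4b had the smallest adjusted p (3.34 ± 0.32, adjusted p = 0.000609), a gene chosen after its values were seen. Limma-voom gave WT N 3 the lowest quality weight of all libraries (0.180), and WT ML 1 had 0.360.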
